A study of Homo sapiens with 4 samples.

How the data were processed

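Total RNA was taken from a pair of lines derived from MDA-MB-231 cells carrying the 7TGP Wnt reporter, grown in DMEM with 10% fetal bovine serum after selection with 3 ug/mL puromycin, and 1 ug of RNA per library went into an Ultra II RNA library kit, per the labels' protocols. All 4 libraries carry the same batch label. The authors deposited a single table of raw read counts per Ensembl gene ID, 1 column per library, which were used as they stand. Column names matched the library titles and gave the line and number of each library, and no other columns of sample values were present.

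HISAT2, Bowtie2 and DESeq2 and the genome build hg19 are named, without versions or roles, per the submitters' processing notes. The counting tool, the annotation and the strand setting are not given in the sources used here. All 43714 gene IDs in the deposited counts are in GENCODE release 29, which is built on GRCh38, and 43289 have a current symbol. The build named in the notes and the annotation that the IDs match therefore differ. The count table holds no coordinates, so positions are those of GENCODE release 29 on GRCh38.

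How reads were assigned was read from the counts. Among 1375 genes with at least 100 counts that lie wholly within a host gene without sharing an exon, 510 on the host's strand and 865 opposite, the host's count was at least that of the inner gene in all 4 libraries in 1375 cases, against at most 1126 in 100 random draws of hosts. RPS29 and RN7SL1, which lies within it, had 1117514 and 1112246 counts in the reporter-negative library numbered 1. Deposited counts thus cover whole gene spans with introns, on both strands, and a read is counted at each gene it overlaps. The spans of 27833 listed genes overlap another listed gene and those of 15881 do not. The overlapping gene with the most counts is named in the text, because reads of such genes cannot be told apart, and is left out where it had few counts relative to the gene itself. Families of near-identical genes are uncertain for the same reason.

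Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by line (minimum count 10, minimum total count 15), the quasi-likelihood fit with robust shrinkage and its F test, line as the only term, and Benjamini-Hochberg adjustment over the 30952 genes kept, at 0.05. CPM values use TMM-scaled library sizes and are given as means with SD over 2 libraries. In the text, a gene rose or fell only if its adjusted p was under 0.05. With 2 libraries per line, the total counts of 55894092 to 63034563 give small counting error for most genes, and the test rests on spread shared across genes. Gene lists and markers of other cell types were fixed before the data were examined, and 20 lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Members were counted over all genes and adjusted over the list alone.

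Genes were named by a rule fixed with the lists: the genes of the series title, the 10 largest rises and 10 largest falls among passing genes with at least 5 CPM in the higher line and no overlap of libraries between lines, up to 4 members per list with the smallest adjusted p (or, where none passed, 2 with the highest CPM), and 4 LINC genes with the smallest adjusted p. Other genes were named after their values were seen: LEF1, CCND1, MYC, CTNNB1, IL6, CCL5, TNFAIP2, SNAI2, ZEB1, FN1, CDH1, HSPA5, HES1, SOX2, MIR3171HG and those given for their position. Not each gene under the rule is discussed.

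Before use, the test was run on simulated counts for the same comparison, drawn for 30359 genes from the real means, library sizes and dispersions with known fold changes. It recovered 30 of 66 genes changed 1.5-fold, 40 of 64 changed 2-fold and 59 of 63 changed 4-fold, and 29 unchanged genes made up 14.9% of its calls. That share lies above the threshold of 0.05. The 38 proliferation genes, raised 1.5-fold, were the only other genes changed, and they count among the calls. In the real data 6942 of 30952 genes were called, a far larger share. Recovery and false calls may depend on how many genes are changed, which was not varied, so these values may not carry over. The share of false calls in the real test is thus not known, and it too may lie above 0.05. Of unchanged simulated genes, 4.79% had an unadjusted p under 0.05. Libraries of the same line differed by more than sampling noise (chi-square per degree of freedom 39.3 and 24.2), so none was a copy of another.

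Alternatives were RLE and total count scaling, no count filter, a filter at 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the library number as a block, leaving out each library, and for lists an estimated correlation and fry. A fit restricted to genes without an overlapping gene was added after the data were seen. Analyses along chromosomes and of gene families used Python 3.11.15 with scipy 1.17.1 and numpy 2.4.6. Trends with GC content and gene-span length were removed from log2 fold changes with a fitted cubic surface.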

Results

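MDA-MB-231 is a human triple-negative breast cancer cell line, meaning that it lacks the oestrogen receptor, the progesterone receptor and HER2 amplification used to class breast tumours. Its cells had been stably transfected with the 7TGP reporter, in which 7 TCF binding sites drive EGFP, so that fluorescence reports transcription through beta-catenin and the TCF/LEF factors, the end of the canonical Wnt pathway. After 8 rounds of expansion and fluorescence sorting, a reporter-positive line of more than 80% EGFP-positive cells and a reporter-negative line of more than 95% EGFP-negative cells were kept. RNA sequencing gave 2 libraries per line, with gene counts totalling 63034563 and 58429705 in the reporter-negative libraries and 62539034 and 55894092 in the reporter-positive libraries. Libraries of the same line correlated at a Spearman coefficient of 0.992 in both lines, and libraries of different lines at 0.980 to 0.983. These coefficients run across the 30952 genes tested below, which are not independent replicates. The labels do not say that the libraries of a line came from separate cultures, so the p-values of single genes and of fry below measure only the spread between these libraries, which may be technical. Those of camera, of the chromosome medians and of the gene families compare genes with other genes and measure no spread between cultures. The chromosome and family tests also treat genes that lie side by side or share reads as independent. With a single line per reporter state, any other difference between the lines cannot be told apart from reporter activity, for genes and lists alike.

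The series title names the long noncoding RNA LINC00645, a microRNA called miR-452 and vimentin, so the comparison asks how the reporter-positive line differs from the reporter-negative line in these genes and in the Wnt, epithelial and mesenchymal programmes around them. In the reporter-positive line, LINC00645 rose 22.2-fold and VIM, the gene of the intermediate filament protein vimentin, fell 2.05-fold. Inflammatory cytokine genes such as IL1B, CXCL8 and CCL2 rose with 23 of the 25 tested members of their list, the Wnt feedback gene AXIN2 rose 1.62-fold, and the collagen-binding integrin gene ITGA11 fell to 0.991% of its reporter-negative level. Cholesterol synthesis genes fell in 13 of 24 cases, and unfolded protein and integrated stress response genes rose in 17 of 25.

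Of 30952 genes tested with edgeR's quasi-likelihood test, 3576 were higher and 3366 lower in the reporter-positive line at a Benjamini-Hochberg adjusted p under 0.05. At least a 2-fold change was seen for 785 of the higher and 470 of the lower genes. Among protein-coding genes, 2491 of 16957 rose and 2508 fell. Higher genes made up 51.5% of the calls with TMM scaling and 36.0% with scaling to total counts, which moved the median log2 fold change of all genes by -0.08. Leaving out the reporter-negative library numbered 1 left 2333 higher and 2025 lower genes. Reads had been counted over whole gene spans, introns included, at each gene they overlapped and on either strand (see the processing), so reads of overlapping genes cannot be told apart, and where such a gene had many counts beside those of a gene described below, it is named.

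**Figure D1:**
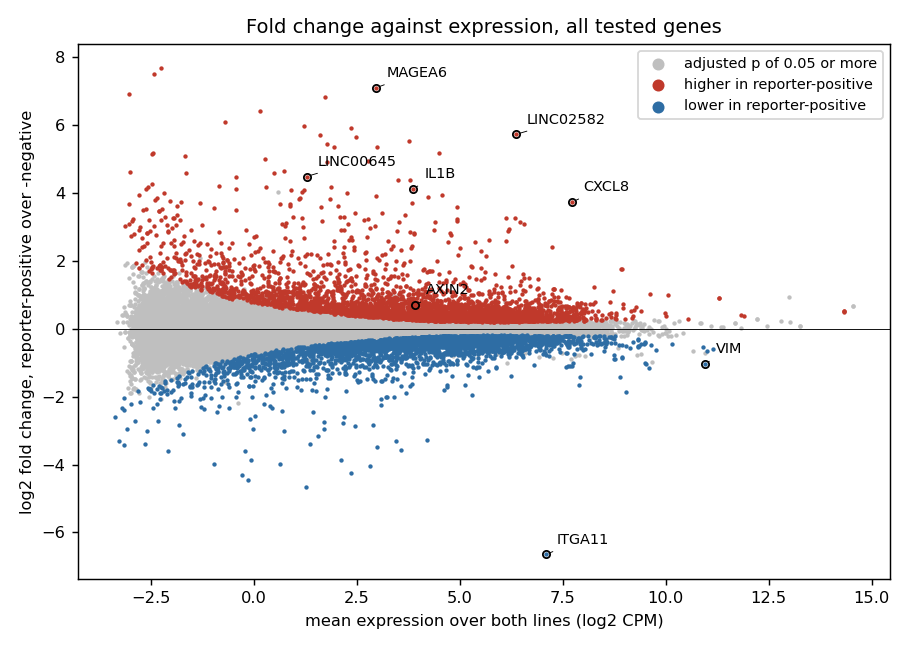
Log2 fold change of the reporter-positive over the reporter-negative line (vertical axis) against mean expression over both lines in log2 CPM (horizontal axis) for the 30952 genes tested. Red and blue points are the 3576 higher and 3366 lower genes, grey points did not pass, and circled points are genes named in the text, among them ITGA11 at -6.65 and MAGEA6 at 7.08.

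LINC00645 (ENSG00000258548, chromosome 14, 27612588 to 27639636 on GRCh38, forward strand) had 11 and 15 counts in the reporter-negative and 336 and 208 in the reporter-positive libraries. Its mean level was 0.209 ± 0.0502 CPM (SD, n = 2) in the reporter-negative and 4.66 ± 0.976 CPM (SD, n = 2) in the reporter-positive line, a log2 fold change of 4.47 with a standard error of 0.27 (edgeR, Benjamini-Hochberg adjusted p = 1.06e-10). LINC00645 lies inside the span of MIR3171HG, a transcribed pseudogene on the opposite strand that hosts a microRNA, and MIR3171HG also rose, from 4.70 ± 1.20 to 56.2 ± 7.94 CPM (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 1.14e-06). In the pooled reporter-positive libraries, counts per kb inside LINC00645 were 1.88 times those in the rest of the host span, with a 95% counting interval of 1.72 to 2.05 that covers counting error only. Reads from LINC00645 and from the host could not be separated beyond that ratio. Other noncoding genes nearby on chromosome 14, named after their values were seen, rose as well, with log2 fold changes of 3.69 for ENSG00000258081, 3.35 for LINC02300 and 1.63 for ENSG00000257869, while the pseudogene BNIP3P1 among them did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.151).

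VIM (ENSG00000026025, chromosome 10, 17228259 to 17237593 on GRCh38) fell from 2670 ± 63.2 to 1300 ± 60.7 CPM (SD, n = 2). Its log2 fold change was -1.04 with a standard error of 0.10 (edgeR, Benjamini-Hochberg adjusted p = 1.91e-07). VIM-AS1 and ENSG00000234961, which overlap VIM on the opposite strand, fell from 986 to 481 and from 963 to 479 CPM. With the counts of both taken from those of VIM, the remainder still fell 2.12-fold, from 720 ± 16.6 to 340 ± 9.37 CPM (SD, n = 2). VIM also lay in a stretch of chromosome 10 where the genes were lower as a group, described further on. MIR452, the microRNA gene of that name, had 0, 4, 2 and 4 counts in the libraries and was too low to test. These few counts cover the gene's span and give no level for miR-452 itself in either line. GABRE, the GABA receptor subunit gene whose span holds MIR452, was at 12.5 ± 0.431 CPM in the reporter-negative and 14.6 ± 2.22 CPM in the reporter-positive line (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 0.128). Without the reporter-positive library numbered 2, GABRE had a log2 fold change of 0.37. With the library number as a block, GABRE passed (edgeR, Benjamini-Hochberg adjusted p = 0.0490). The block leaves fewer degrees of freedom for the spread between libraries, so this p was not taken as support.

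**Figure D2:**
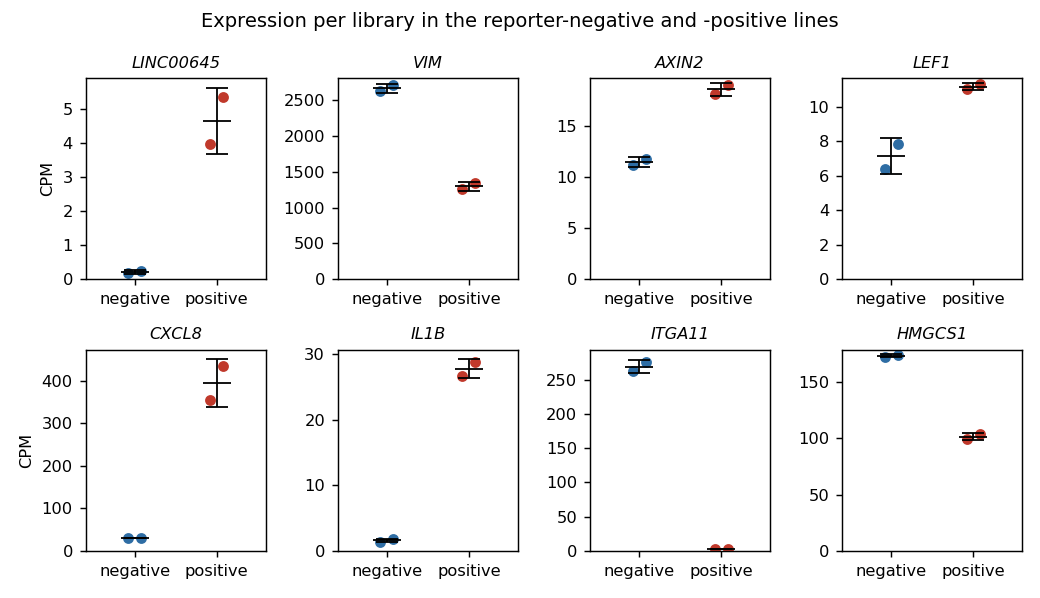
CPM (vertical axes, starting at 0) of 8 genes in the 2 reporter-negative (blue) and 2 reporter-positive (red) libraries. Points are libraries, the long bar is the mean and the whiskers are 1 SD, and the libraries of the lines do not overlap in any panel, with LINC00645, AXIN2, LEF1, CXCL8 and IL1B higher and VIM, ITGA11 and HMGCS1 lower in the reporter-positive line.

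Direct Wnt/beta-catenin target genes moved both ways. Of 27 tested members, 9 rose, 3 fell and 15 did not pass, and adjusted over the list alone 9 rose and 5 fell. AXIN2, a negative feedback regulator that is among the most general targets of the pathway, rose from 11.4 ± 0.450 to 18.5 ± 0.652 CPM (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 5.26e-06), and overlaps ENSG00000266076, whose counts reached 62.1% of its own. LGR6, a receptor for R-spondins, rose 4.61-fold and the growth factor gene BMP4 rose 1.63-fold, from 121 to 197 CPM. LEF1, which encodes a partner of beta-catenin on DNA and overlaps LEF1-AS1, rose 1.57-fold. The transcription factor gene SOX9, which overlaps SOX9-AS1, fell by 0.47 and the cyclin gene CCND1, which overlaps LTO1, fell by 0.50 on the log2 scale. MYC stood at 68.8 ± 0.519 CPM in the reporter-negative and 74.9 ± 2.91 CPM in the reporter-positive line (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 0.249), and passed without the reporter-positive library numbered 1 (adjusted p = 0.0383 by the same test). As a set the list was not called by camera, which compares a list with all other genes (Benjamini-Hochberg adjusted p = 0.219), while fry, which tests whether the members move one way on balance, called it up (Benjamini-Hochberg adjusted p = 0.0470).

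Wnt ligands, receptors and intracellular components, 53 of them tested, included 5 that rose, 12 that fell and 36 that did not pass (5 and 13 adjusted over the list alone). The ligand gene WNT7B rose 1.97-fold, from 26.1 to 51.5 CPM, and the receptor gene ROR1, which overlaps ROR1-AS1, rose 1.43-fold. WNT9A fell by 1.57 and the receptor gene FZD1 fell by 0.81 on the log2 scale. CTNNB1, which encodes beta-catenin, rose from 514 ± 14.2 to 659 ± 53.3 CPM (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 0.00466), a call that was lost without either reporter-negative library (adjusted p = 0.234 and 0.137 by the same test). The list was not called by camera (Benjamini-Hochberg adjusted p = 0.219) and was called down by fry (Benjamini-Hochberg adjusted p = 0.0298).

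Inflammatory cytokine and NF-kappaB target genes rose almost throughout. Of 25 tested members 23 rose, none fell and 2 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was 1.61. CXCL8, the gene of the neutrophil attractant interleukin 8, rose 13.3-fold from 29.8 ± 0.205 to 395 ± 56.1 CPM (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 4.86e-15). IL1B, which encodes interleukin 1 beta, rose 17.4-fold to 27.8 ± 1.45 CPM, and CCL2, a monocyte attractant, rose 52.3-fold from 0.112 ± 0.0253 to 5.97 ± 0.162 CPM (SD, n = 2). CXCL1, whose sequence is close to those of CXCL2 and CXCL3 so that reads may be shared, rose 9.48-fold, and the granulocyte colony-stimulating factor gene CSF3 rose 5.85-fold. IL6, which overlaps the far more highly counted STEAP1B, rose 8.39-fold. The members that did not pass were CCL5, which overlaps ENSG00000270240, at 0.604 and 0.390 CPM, and TNFAIP2, at 91.2 and 95.3 CPM, in the reporter-negative and reporter-positive line. Camera called the list up (Benjamini-Hochberg adjusted p = 6.22e-30; adjusted p = 0.118 with an estimated correlation).

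**Figure D3:**
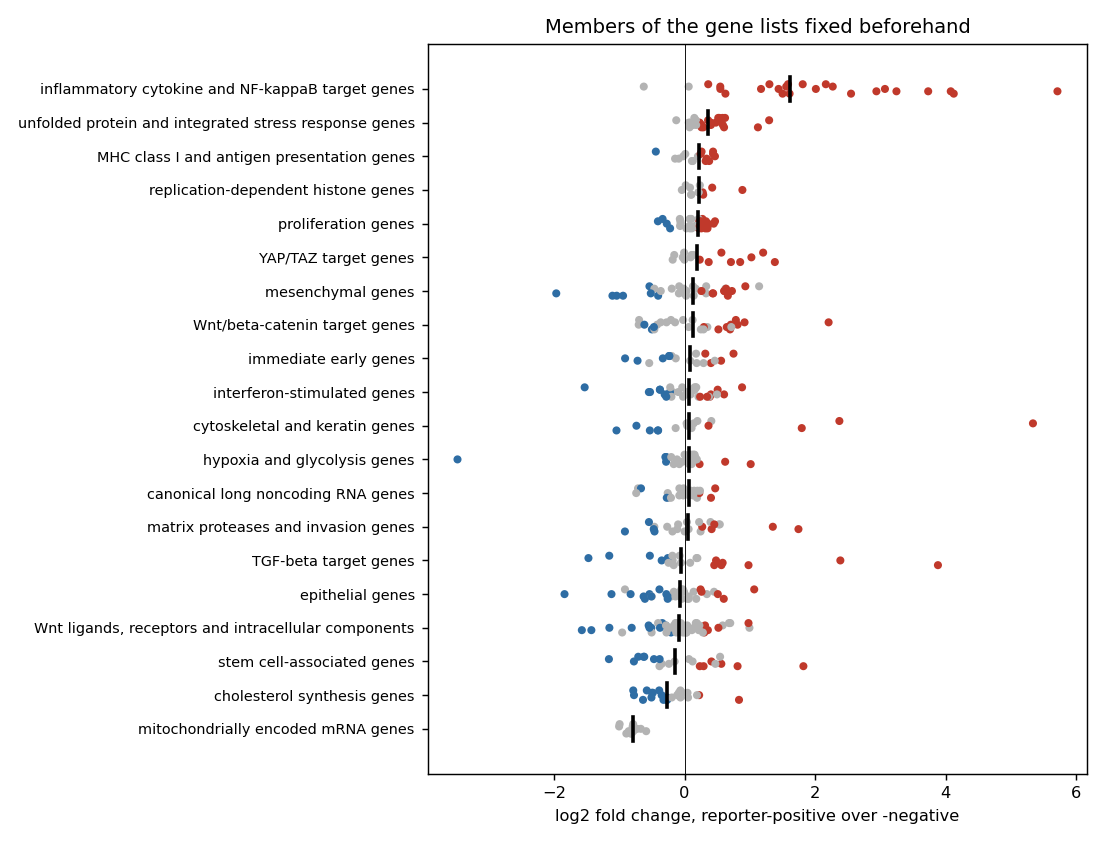
Log2 fold change, reporter-positive over reporter-negative (horizontal axis), of each tested member of the 20 gene lists fixed beforehand (vertical axis). Red points rose, blue points fell, grey points did not pass, and the black bar is the list's median, highest for the inflammatory cytokine list at 1.61 and lowest for the mitochondrially encoded mRNA genes at -0.79.

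Mesenchymal genes were split. Of 33 tested members 9 rose, 7 fell and 17 did not pass (10 and 7 adjusted over the list alone). VIM and the collagen VI genes were among those that fell: COL6A3 fell 3.90-fold from 62.4 ± 3.10 CPM and COL6A2 fell 1.92-fold from 34.7 ± 1.02 CPM (SD, n = 2), and the integrin gene ITGB3, which overlaps ENSG00000259753, fell by 1.10 on the log2 scale. SNAI2, which encodes the transcription factor Slug, rose 1.55-fold, from 10.4 to 16.2 CPM. ZEB1 and FN1 did not pass, at 133 and 125 CPM and at 680 and 674 CPM in the reporter-negative and reporter-positive line. The list's median and mean were 0.13 and 0.02, camera did not call it (direction up, Benjamini-Hochberg adjusted p = 0.840), and fry called it down (Benjamini-Hochberg adjusted p = 0.0470).

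Epithelial genes more often fell: of 33 tested members 5 rose, 11 fell and 17 did not pass, with the same counts adjusted over the list alone. MUC1, a membrane mucin gene that overlaps ENSG00000273088, fell by 1.84 and the keratin gene KRT19 fell by 0.54 on the log2 scale. TJP1, a tight junction gene that overlaps HMGN2P5, rose 1.52-fold, from 81.0 to 123 CPM. CDH1, the E-cadherin gene, which overlaps ENSG00000260798, was at 0.588 ± 0.274 and 0.748 ± 0.157 CPM in the reporter-negative and reporter-positive line (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 0.572). Camera did not call the list (Benjamini-Hochberg adjusted p = 0.136), but called it down among genes without an overlapping gene (adjusted p = 0.00776 by the same test), with 13 members left. Fry called it down too (Benjamini-Hochberg adjusted p = 0.0298). Of 21 tested stem cell-associated genes 6 rose, 7 fell and 8 did not pass (6 and 8 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.244, and 0.0111 without the reporter-positive library numbered 2). Those that fell included the intermediate filament gene NES, from 58.4 to 26.2 CPM, the pluripotency factor gene KLF4, from 34.7 to 21.3 CPM, and NOTCH1, from 73.4 to 47.8 CPM. Those that rose included HES1, a transcriptional repressor gene in Notch signalling, from 7.07 to 10.5 CPM, and the pluripotency factor gene SOX2, which overlaps SOX2-OT and rose 3.53-fold from a low level, from 0.249 to 0.880 CPM; both were named after their values were seen.

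TGF-beta target genes moved both ways, with 7 of 21 members higher, 5 lower and 9 not passing (9 and 8 adjusted over the list alone). INHBA, which encodes an activin subunit and overlaps INHBA-AS1, rose 14.7-fold from 2.40 ± 0.158 to 35.3 ± 1.87 CPM (SD, n = 2), and TGFBI, a secreted matrix protein gene, rose 5.23-fold from 10.3 ± 0.517 to 53.7 ± 0.0901 CPM (SD, n = 2). ID1, a differentiation inhibitor and BMP target gene, fell by 1.47 on the log2 scale. The list's median was -0.05 and its mean 0.24, and camera did not call it (direction up, Benjamini-Hochberg adjusted p = 0.227), although each of the 4 fits without a single library did, with adjusted p from 1.19e-05 to 0.00756 by the same test. It was also called up with the library number as a block (camera, Benjamini-Hochberg adjusted p = 0.0218) and by fry (Benjamini-Hochberg adjusted p = 0.0342). The block and the fits without a single library leave fewer degrees of freedom for the spread between libraries, so neither was taken as support. YAP/TAZ target genes rose in 8 of 16 cases and none fell, with the same counts adjusted over the list alone. The clotting initiator gene F3 rose from 71.8 ± 2.31 to 165 ± 6.96 CPM and ANKRD1 from 100.1 ± 4.23 to 203 ± 8.25 CPM (SD, n = 2), and camera called the list up (Benjamini-Hochberg adjusted p = 2.61e-05; adjusted p = 0.574 with an estimated correlation). Matrix proteases and invasion genes gave 5 higher, 4 lower and 13 not passing of 22, with 5 and 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.840). The collagenase gene MMP1, which overlaps WTAPP1, rose 3.35-fold from 223 to 747 CPM, and the cathepsin gene CTSL fell by 0.91 on the log2 scale.

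Unfolded protein and integrated stress response genes rose in 17 of 25 cases and none fell (18 adjusted over the list alone). The mTORC1 inhibitor gene DDIT4, which overlaps DDIT4-AS1, rose 2.45-fold, the protein disulphide isomerase gene PDIA4 rose 2.18-fold from 112 ± 2.83 to 243 ± 22.6 CPM (SD, n = 2), and the chaperone gene HSPA5 rose 1.43-fold, though it lay in a block of lower genes on chromosome 9. Camera called the list up (Benjamini-Hochberg adjusted p = 1.12e-09; adjusted p = 0.574 with an estimated correlation). Cholesterol synthesis genes went the other way, with 2 higher, 13 lower and 9 not passing of 24 (3 and 14 adjusted over the list alone). HMGCS1, an early enzyme of the pathway that overlaps ENSG00000261604, fell from 174 ± 1.10 to 102 ± 2.87 CPM (SD, n = 2), IDI1, which overlaps IDI2-AS1, fell by 0.79 and FDFT1 fell by 0.58 on the log2 scale. INSIG1, whose product restrains the pathway, rose 1.78-fold. Camera called the list down (Benjamini-Hochberg adjusted p = 8.19e-05; adjusted p = 0.574 with an estimated correlation). Among genes without an overlapping gene, a test added after the data were seen, camera did not call it (adjusted p = 0.303), with only 9 members left.

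Proliferation genes rose in 17, fell in 4 and did not pass in 17 of 38 cases (22 and 4 adjusted over the list alone), and their changes were small: RRM2, a ribonucleotide reductase gene that overlaps AC007240.1, rose 1.38-fold and BIRC5, the survivin gene, rose 1.28-fold, while the cell cycle factor gene E2F1 fell by 0.41 on the log2 scale. Camera called this list up (Benjamini-Hochberg adjusted p = 6.52e-04; adjusted p = 0.664 with an estimated correlation). The call was lost without the reporter-positive library numbered 2, and among genes without an overlapping gene (adjusted p = 0.179 by the same test), with only 18 members left. Replication-dependent histone genes, which include near-identical copies, rose in 4 of 12 cases and none fell (5 adjusted over the list alone), with H3C13 up 1.85-fold, and camera called them up (Benjamini-Hochberg adjusted p = 0.00496; adjusted p = 0.683 with an estimated correlation), but not without the reporter-positive library numbered 2 (adjusted p = 0.246 by the same test). MHC class I and antigen presentation genes rose in 8 and fell in 1 of 16 cases (9 and 1 adjusted over the list alone). The overlapping pair PSMB9 and TAP1, an immunoproteasome subunit and a peptide transporter gene, rose by log2 fold changes of 0.47 and 0.44, and the class I transactivator gene NLRC5, which overlaps ENSG00000260145, fell by 0.44 on the log2 scale. Camera called this list up (Benjamini-Hochberg adjusted p = 0.00983; adjusted p = 0.625 with an estimated correlation), but not without the reporter-negative library numbered 1 or the reporter-positive library numbered 2 (adjusted p = 0.0876 and 0.129 by the same test).

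Interferon-stimulated genes showed no common direction, with 7 higher, 8 lower and 21 not passing of 36, and the same 7 and 8 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.765). IFI27 rose 1.52-fold and IFI44L rose 1.84-fold, while USP18, which encodes an ISG15 protease, fell by 1.53 on the log2 scale. Hypoxia and glycolysis genes gave 3 higher, 4 lower and 19 not passing of 26 (3 and 6 adjusted over the list alone), with median 0.06 and mean -0.08 (camera, direction up, Benjamini-Hochberg adjusted p = 0.840). The aldolase gene ALDOC, which overlaps ENSG00000258472, fell from 14.7 ± 0.345 to 1.31 ± 0.152 CPM, and the peptide hormone gene ADM rose from 13.8 ± 0.480 to 27.8 ± 1.32 CPM (SD, n = 2). Of 17 immediate early genes 4 rose, 5 fell and 8 did not pass (6 and 6 adjusted over the list alone; median 0.09, mean -0.00394; camera, direction up, Benjamini-Hochberg adjusted p = 0.840), with IER3, which overlaps IER3-AS1, up 1.68-fold and KLF2 down by a log2 fold change of -0.91.

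Mitochondrially encoded mRNA genes were lower on average but variable between libraries. None of the 13 passed, over all genes or adjusted over the list alone, and their median log2 fold change was -0.79. MT-ND4, a complex I subunit gene that overlaps MT-ND4L, was at 1073 ± 232 CPM in the reporter-negative and 539 ± 253 CPM in the reporter-positive line (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 0.385). Mitochondrial genes held 0.556% and 0.770% of all counts in the reporter-negative and 0.477% and 0.280% in the reporter-positive libraries. Camera called the list down (Benjamini-Hochberg adjusted p = 4.20e-08; adjusted p = 0.574 with an estimated correlation). MT-ND4 had 57703 and 75962 counts in the reporter-negative and 45061 and 18851 in the reporter-positive libraries. In the 4 fits without a single library its log2 fold change ran from -1.57 to -0.59. Passes in those fits are not given for mitochondrial genes, as 1 line then holds a lone library. With all libraries, MT-ND4 passed with limma-voom (adjusted p = 0.00173) and with the library number as a block in edgeR (adjusted p = 2.70e-19). The block leaves fewer degrees of freedom for the spread between libraries, so its p was not taken as support. MT-CO1, with a main adjusted p of 0.137 from edgeR, likewise passed with limma-voom (adjusted p = 0.00360) and with the block in edgeR (adjusted p = 8.79e-07). Its log2 fold change was -0.99 without the reporter-positive library numbered 1 and -0.41 without that numbered 2. Genes named after the 7SL RNA, an abundant small cytoplasmic RNA, held 6.05% and 3.92% of counts in the reporter-negative and 6.82% and 7.46% in the reporter-positive libraries.

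Long noncoding RNAs changed strongly in places. Of 1080 tested genes with a LINC symbol, 119 rose and 74 fell, and 70 and 35 of these changed at least 2-fold. Among the 570 that overlap no other gene, 61 rose and 39 fell. LINC02582, on chromosome 18 and without an overlapping gene, rose 52.5-fold from 3.08 ± 0.392 to 162 ± 3.43 CPM (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 3.33e-19). LINC02864, also on chromosome 18, rose 20.9-fold and LINC02506 on chromosome 4 rose 7.51-fold. LINC00632 rose 35.6-fold, from 1.23 to 44.0 CPM. CDR1, which lies within the span of LINC00632 on chromosome X, rose 45.7-fold, from 0.585 to 26.8 CPM. Counts of LINC00632 include those of CDR1, so these rises are not separate and their reads cannot be told apart. The canonical long noncoding RNA genes, a list with MALAT1, NEAT1 and others, gave 3 higher, 2 lower and 20 not passing of 25 (2 and 2 adjusted over the list alone; median 0.06, mean -0.04; camera, direction up, Benjamini-Hochberg adjusted p = 0.909). Without the reporter-positive library numbered 1, camera called this list down (adjusted p = 0.00247 by the same test). FTX, which overlaps JPX, rose 1.39-fold, and MIR210HG, which overlaps MIR210, fell by 0.67 on the log2 scale.

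Among genes with at least 5 CPM in the higher line, the largest rises were those of the cancer-testis antigen genes MAGEA6 and MAGEA3 on chromosome X, near-identical copies whose reads may be shared. MAGEA6 rose from 0.113 ± 0.0479 to 15.5 ± 1.54 CPM and MAGEA3 from 0.0564 ± 0.0353 to 6.57 ± 0.142 CPM (SD, n = 2). LINC00839 rose 59.7-fold, the neuronal membrane protein gene SLITRK6 50.2-fold, the vitamin D 24-hydroxylase gene CYP24A1 43.4-fold, the prostate-specific membrane antigen gene FOLH1 40.6-fold and the hair keratin gene KRT81, which overlaps and resembles KRT86, 40.3-fold. ITGA11, the gene of integrin alpha 11, showed the largest fall among genes past the expression limit, from 269 ± 10.1 to 2.66 ± 0.421 CPM (SD, n = 2; log2 fold change -6.65 with a standard error of 0.11; edgeR, Benjamini-Hochberg adjusted p = 1.99e-19). The trefoil factor gene TFF2 fell from 9.86 to 0.498 CPM, the prohormone convertase inhibitor gene PCSK1N from 13.3 to 0.794 CPM and the phosphatase subunit gene PPP2R2C from 22.2 to 1.87 CPM. SORL1, a sorting receptor gene, went from 19.9 to 1.99 CPM and SCNN1A, a sodium channel subunit gene that overlaps LTBR, from 33.5 to 3.46 CPM. NDP, which encodes a ligand of the Wnt receptor FZD4 and overlaps NDP-AS1, fell from 5.32 ± 0.170 to 0.586 ± 0.0725 CPM (SD, n = 2), and DCAF8L2 fell by 2.97 on the log2 scale. ENSG00000265168, an antisense gene that overlaps ALDOC, fell by 3.86 on the log2 scale.

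Cytoskeletal and keratin genes gave 4 higher, 5 lower and 7 not passing of 16 (5 and 5 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.765), and fry called the list up (Benjamini-Hochberg adjusted p = 0.0342). KRT86, which overlaps KRT7 and holds KRT81 within its span, rose 5.17-fold, from 4.58 to 23.7 CPM. Its counts include those of KRT81, which rose from 0.384 to 15.6 CPM, so its rise is in large part that of KRT81. The muscle-type genes TPM2 and MYL9, the latter overlapping DLGAP4-AS1, fell by 1.04 and 0.74 on the log2 scale. Luminal breast markers gave 4 higher, 7 lower and 5 not passing of 16, also when adjusted over the list alone, with the trefoil factor gene TFF3 down from 4.69 ± 0.461 to 0.442 ± 0.00485 CPM (SD, n = 2). Basal markers gave 3 higher, 3 lower and 2 not passing of 8, also when adjusted over the list alone, with TP63 up 3.66-fold and MYLK, which overlaps MYLK-AS1, down by a log2 fold change of -0.70. Markers of cells that this culture should not hold were counted but not tested as sets. Of 8 tested immune markers none rose and 3 fell (1 and 4 adjusted over the list alone), among them LYZ, which overlaps ENSG00000257764, from 4.76 to 2.05 CPM, of 8 endothelial markers 1 rose and none fell, of 10 fibroblast markers 1 rose and 2 fell, and of 5 kidney embryonic line markers none rose and 2 fell, with equal counts adjusted over these 3 lists alone.

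Camera called 8 of the 20 lists, 6 up and 2 down, and with an estimated correlation it called 0 of them, at n = 2 per line. Fry called 10 lists, 4 of them among these 8, and did not call the MHC class I, proliferation, histone and mitochondrially encoded lists (Benjamini-Hochberg adjusted p = 0.0973, 0.116, 0.276 and 0.271).

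Fold changes were not spread evenly along the chromosomes. Among 14367 protein-coding genes with a mean of at least 1 CPM, the median log2 fold change relative to all of them was 0.32 on chromosome X, -0.28 on chromosome 9 and -0.25 on chromosome 20 (permutation test with 10000 random gene sets per chromosome, two-sided, Benjamini-Hochberg adjusted p = 0.000164 over 23 chromosomes for each, from the smallest p that these sets can give). Of the 23 chromosomes 19 passed, but once trends with GC content and gene length were removed, 6 of the 16 others that passed lay within the range of random gene sets and 2 had the opposite sign. Among genes that overlap no other, 8 of these 16 no longer passed an unadjusted p of 0.05 in the same kind of test, with 50 to 293 such genes on each. Only 2 of these 8 medians kept under 50% of their size. In a running median over 41 genes, 16 blocks of at least 20 genes stood out, 6 higher and 10 lower. The block with the most negative median, -0.73, ran from 140.8 to 141.6 Mb on chromosome 5 over the protocadherin gene clusters, whose genes overlap and share reads. A lower block of 84 genes on chromosome 6, from 41.05 to 53.1 Mb, had a median of -0.57. The highest median, 0.56, was that of a block of 73 genes on chromosome 17, from 14.3 to 21.3 Mb. The longest block, higher in the reporter-positive line with a median of 0.53, ran from 53.0 to 153 Mb on chromosome X and held GABRE, MAGEA3, MAGEA6, CDR1, LINC00632, FTX and the glycolysis gene PGK1, which overlaps ATP7A and rose 1.54-fold. VIM lay in a lower block on chromosome 10, from 5.86 to 18.5 Mb, with a median of -0.36. The lower block on chromosome 20, with a median of -0.33, held ID1, E2F1, MYL9 and CYP24A1, and that on chromosome 15, with a median of -0.43, held ITGA11. Lower blocks on chromosome 9 held NOTCH1, HSPA5, CTSL and TPM2 and one on chromosome 16 held NLRC5, while higher blocks held MMP1 and SORL1 on chromosome 11, FOLH1 on chromosome 11 and PDIA4 on chromosome 7.

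**Figure D4:**
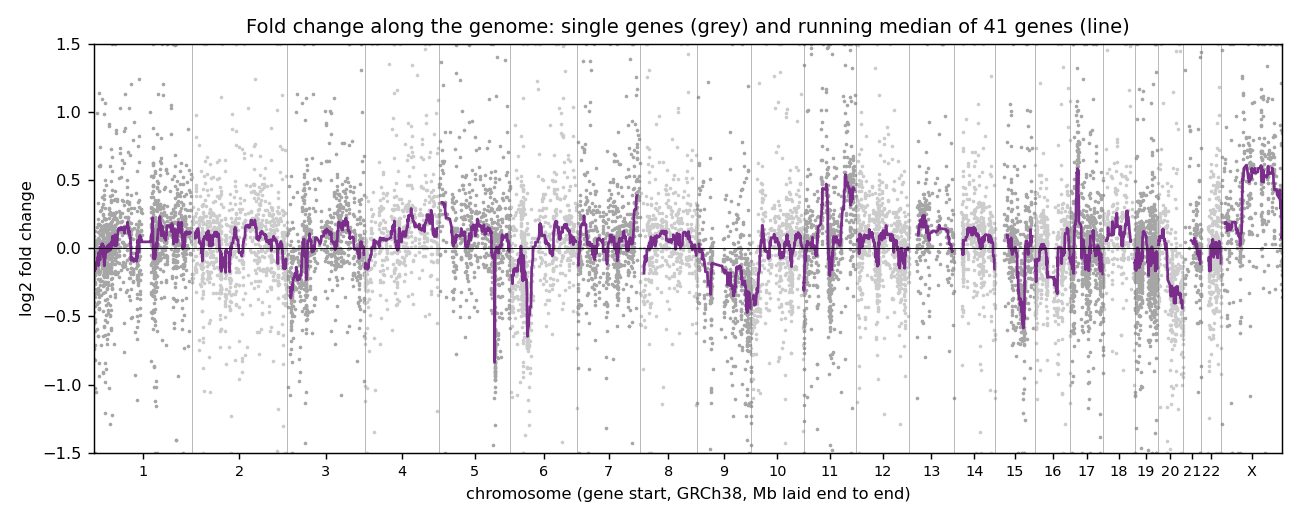
Log2 fold change, reporter-positive over reporter-negative (vertical axis, limited to the range shown), of expressed protein-coding genes by position on GRCh38 (horizontal axis, chromosomes laid end to end). Grey points are genes and the line is the running median of 41 genes, which lies above 0 over much of chromosome X and below 0 over much of chromosomes 9 and 20.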

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

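The fit restricted to genes without an overlapping gene was chosen only after the results were seen, and the other alternatives were set before the data were examined. LINC00645 and VIM kept their direction and passed in all alternatives that tested them, with log2 fold changes from 4.24 to 4.73 and from -1.12 to -0.99. Scaling to total counts gave 2270 genes higher in reporter-positive cells against 3576 with TMM, and 4032 against 3366 lower; it shifts the genes down as a whole, by a median of -0.08. Leaving out single libraries gave 2333 to 4704 higher, 2025 to 4457 lower, 1206 to 1444 changed at least 2-fold and 144 to 202 LINC-prefixed genes changed, the lowest counts of higher and lower genes being those without the reporter-negative library numbered 1; a lone library is then assumed to vary like the other line. The fit on genes without an overlapping gene tested 9888 genes and gave 1111 higher and 1093 lower, 525 changed at least 2-fold and 99 LINC-prefixed genes, because fewer genes entered it; of the 2185 calls it could test it kept 2130. A filter at 1 CPM in 2 libraries gave 817 genes changed at least 2-fold against 1255, with 22016 genes tested. DESeq2 gave 109 LINC-prefixed genes changed against 193, with an adjusted p withheld by its own filter for 6601 of all genes tested, though the cause of the lower count was not tested.

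Of the fixed gene lists, 0 were called with an estimated correlation against 8 with the preset value, and 7 to 10 without single libraries; fry, which asks another question, called 10, of which 4 were shared. The mesenchymal genes turned from up to down with fry (adjusted p = 0.0470, against 0.195 to 0.939 in the other alternatives), and the canonical long noncoding RNA genes turned down without the reporter-positive library numbered 1 (adjusted p = 0.00247, with 0.00247 to 0.953 over the fits without single libraries), with the cause not tested in either case. No named gene with a call changed direction. Genes without a call in either setting were given no direction, a rule set after some were seen to change sign: FN1 to 0.07 without the reporter-positive library numbered 1, CDH1 to -0.07 without the reporter-negative library numbered 1, TNFAIP2 to -0.02 with total count scaling and CCL5 to 0.04 without the reporter-negative library numbered 2. The most calls of named genes were lost without a reporter-negative library, 11 without that numbered 1 and 9 without that numbered 2, against 5 with DESeq2 and 4 with scaling to total counts. Across genes, the deviations of the libraries numbered 1 from their line means correlated at -0.026, so no pairing by library number was seen. A single correlation over genes cannot exclude a shared preparation. Adding the replicate block gave 8226 calls against 6942, of which 6935 were shared. With 2 simulated libraries per line at the real depth, 30 of 66 genes changed 1.5-fold were recovered. Far fewer genes were changed there than were called in the real data, and depth was not varied.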

Other observations

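The chromosome blocks, the runs of genes and the families were looked at only after the results were seen, as were the tests of whether copy loss accounts for the whole fall in VIM, of the host gene of LINC00645, of GC content and gene length in the blocks and on chromosomes other than 9, 20 and X, and of counting of reads at several genes on those other chromosomes; predictions for the other tests were written before their results. Genes changed at least 2-fold lay next to each other more often than in random orders of the genes: 19 runs of at least 4 adjacent genes, 18 of them higher in the reporter-positive line, against at most 1 in 100 random orders, and 5 runs against 0 among genes that overlap no other. These 5 runs held PTGS2 with PLA2G4A, which both act in prostaglandin synthesis, on chromosome 1, SLITRK6 and SLITRK5 on chromosome 13, a stretch of pseudogenes and unnamed genes on chromosome 2, and the 12 near-identical CT47A cancer-testis genes on chromosome X, which may count reads of the same origin and whose log2 fold changes ran from 2.44 to 3.33 while the block around them had a median of 0.53.

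Of 14 gene families examined after the data were seen, the protocadherin genes stood out: 47 of 64 fell and 4 rose, with a median of -0.71, and all 47 falls were among the 54 on chromosome 5, while 2 rises each were on chromosomes 4 and 13 (Fisher's exact test against other protein-coding genes, Benjamini-Hochberg adjusted p over 28 tests = 1.91e-24). The median was -0.70 and -0.79 with RLE and total count scaling, and -0.70 with DESeq2. Protocadherin genes on chromosome 5 lie mostly in a single lower block and share overlapping spans, so that a read is counted at several of them and the fall is that of a locus, not of independent genes. Zinc finger genes named ZNF were the other family past the threshold, with 35 of 498 risen, a smaller share than of other protein-coding genes (adjusted p = 2.17e-06 by the same test), and 62 fallen (adjusted p = 0.406). With total count scaling 16 rose and 79 fell, and with DESeq2 25 rose and 42 fell.

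A candidate explanation for the blocks along the chromosomes, formed on the same data, is a difference in DNA copy number between the sorted lines, and shared regulation of neighbouring genes stays open beside it, as no DNA was measured here. Log2 fold changes of adjacent protein-coding genes that overlap no other gene correlated at 0.316 by rank, against at most 0.0545 in 1000 random orders, and at 0.265 without chromosomes 9, 20 and X. For chromosomes 9, 20 and X the tables argue against trends with GC content and gene length, after whose removal they kept at least 84.8% of their medians and the 16 blocks 79.6% to 125.2%, and against counting of reads at several genes, since genes without overlap kept at least 93.0%. Of the 16 other chromosomes that passed, chromosomes 1, 6, 7, 11, 14, 15 and 18 kept at least 69.1% of their medians without these trends. They also stayed beyond the range of random gene sets. This group was picked by that result, so it gives no separate test of such trends. On the remaining 9, 6 medians lay within that range, 2 turned sign and 1 kept under 50% once the trends were removed. There the trends cannot be told apart from other causes. Among genes without overlap, chromosomes 1, 4, 5, 7, 13, 16, 17 and 19 kept at least 74.0% of their medians (unadjusted permutation p under 0.05 on each). These too were picked by that result, which therefore gives no separate test of counting at several genes. On chromosomes 2, 6, 8, 11, 14, 15, 18 and 22 the 50 to 293 genes without overlap did not pass that test. The medians of chromosomes 2, 6, 8, 14, 15 and 18 still kept 62.15% to 114.7% of their size, so there the pass was lost but most of the shift was not. The other 2 medians kept under 50%, that of chromosome 11 being 0.447% of its size and that of chromosome 22 of opposite sign. Counting at several genes cannot be told apart from other causes on these 8 chromosomes.

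As the whole of the fall in VIM, copy loss in the block on chromosome 10 is argued against, since 0% of its 52 other genes were as low as VIM and their median was -0.36. A smaller part for copy loss might remain: the 40 nearest protein-coding genes had a median log2 fold change of -0.29 (95% bootstrap interval -0.36 to -0.17), between the values set beforehand for and against it. Reads from the overlapping antisense genes fell by 72.2% of the fall in VIM, past the 50% set beforehand as a sign that they cause it. Where they overlap VIM they cannot be told apart from its reads, because the counting ignored strand, so VIM's own reads are counted at these genes too. The remainder of VIM without their counts fell 2.12-fold, from 720 ± 16.6 to 340 ± 9.37 CPM (SD, n = 2). That argues against them as the whole cause of the fall. Regulation of VIM that goes with reporter activity, the biological difference the design names, stays open and untested.

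For the higher LINC00645 count, reads from the host gene MIR3171HG on the opposite strand could account for part of it. The rest of the host span rose 11.5-fold where LINC00645 rose 22.3-fold, and density inside LINC00645 was 1.88 times that of the rest in the reporter-positive libraries (95% counting interval 1.72 to 2.05). In the reporter-negative libraries the ratios were 0.972 and 0.952, with intervals of 0.479 to 1.77 and 0.527 to 1.59. A density above that of the host leaves a part of the rise to LINC00645 or to uneven coverage of the host, and these cannot be told apart without strand, so the biological difference between the lines stays open as well.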
